A study of Homo sapiens with 24 samples.

How the data were processed

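Primary human monocytes were enriched from the blood of healthy donors with an antibody cocktail that removes other blood cells (RosetteSep), per the labels. The cells were kept in 0.5% serum, pretreated for 30 min, and exposed for 1 h to vehicle (DMSO), to R848 at 0.5 ug/ml, or to R848 after PF-06426779 at 1 uM. Biotin-labelled cRNA was made from 6 ug of total RNA and hybridized to Affymetrix human arrays, per the labels' protocols. The deposited table holds 1 intensity value (signal) for each of 54675 probe sets on each array, on a linear scale, and the values were made with MAS5, per the submitters' processing notes, which give no version. The median signal over all probe sets was 100 on each of the 24 deposited arrays, so the authors had already scaled them to a common median. How that scaling was done and in which batches the arrays were scanned are not given in the sources used here. The structure of PF-06426779 is likewise not given, and its description as an IRAK4 inhibitor comes from the labels.

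Groups were taken from the treatment labels as DMSO (8 arrays), R848 (9) and R848 + PF-06426779 (7), and no column of the table was left out. Values were used as log2(signal + 20) with no further scaling. Left out of the tests on genes were 1801 probe sets with several gene symbols, 11777 with none and the 62 control probe sets, which are counted within the symbol classes. Of the 41097 probe sets with 1 symbol, 41043 matched a RefSeq gene (assembly GRCh38.p14) by gene ID, which was used for names alone and updated 0 symbols. For each of 19775 genes the probe set with the highest mean was kept, and the 11865 genes in the upper 60% by mean over all arrays were tested, while the 7910 below a mean of 6.58 on the log2 scale (a signal of 75.7) were not. Of the tested genes 4127 had 1 probe set. CCL3 is measured only by a probe set that carries several symbols, and IRAK4 was not analysed here.

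Comparisons were made with limma 3.58.1 in R 4.3.3, R848 against DMSO, R848 + PF-06426779 against R848, and R848 + PF-06426779 against DMSO. A linear model with 1 mean per group was fitted to all 24 arrays with moderated variances (lmFit and eBayes), tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within a comparison with a threshold of 0.05. The p-values measure the spread between these arrays from healthy donors. The number of arrays limits the precision, and the SE given with each change comes from the fit. The titles number the arrays within each group from 1 to 9, with 6 of the 9 numbers present in all groups, and the labels do not say what the number stands for. After group means were removed, 21 pairs of arrays with the same number in different groups correlated at 0.405 to 0.801 (median 0.601), whereas 170 pairs with different numbers had a median of −0.0894 (−0.423 to 0.44). All 24 arrays correlated best with an array of their own number. The main fit takes the arrays as independent, so its p-values count differences between the numbers as spread. The fit with the number as a block (a fixed effect) is therefore given beside the counts, and the pairs show how many of them share a direction.

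Gene lists, 21 in all, were fixed before the data were examined, as were the comparisons, the test, the filter, the rule for named genes and most of the alternatives tried. They were inflammatory cytokines, chemokines, NF-kB target and feedback genes, immediate-early genes, MAPK phosphatase and feedback genes, JAK-STAT feedback genes, interferon-stimulated genes, type I and III interferons, genes linked to IRF5 in the literature, TLR7/8 signalling components, Toll-like and other pattern receptors, apoptosis regulators, glycolysis, cytosolic ribosomal proteins, heat shock and stress genes, and markers of monocytes, T cells, NK cells, B cells and plasmacytoid dendritic cells, platelets and red cells, and granulocytes. Each was tested against the other genes with limma's camera at its preset correlation of 0.01, adjusted over the 21 lists of a comparison, and members were counted over all genes tested and adjusted over the list alone. Named genes were the 10 largest rises and 6 largest falls for R848 against DMSO, the 10 largest falls and 6 largest rises for inhibitor against R848, and the 5 largest of each for inhibitor against DMSO. Added to these were up to 4 members of each list with the lowest p in each of the first 2 comparisons and a fixed set of cytokine, chemokine and TLR pathway genes. Genes named outside this rule are said to have been named after their values were seen.

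The share of the R848 response left with the inhibitor was the inhibitor-minus-DMSO change over the R848-minus-DMSO change, both on the log2 scale, for genes that passed and changed at least 2-fold. Intervals were 95%, from 1000 bootstrap draws of arrays within groups for medians and from Fieller's method for single genes. The overlap between the R848 and inhibitor comparisons was set against independent lists, against 100 simulations of unchanged groups that share the R848 arrays, and against 100 splits of those arrays. The pipeline was tested on simulated data with 200 changed genes among 11865. For R848 against DMSO, limma recovered 11.3% of genes changed 1.5-fold, 64.5% of those changed 2-fold and 97.4% of those changed 4-fold. For inhibitor against R848 it recovered 7.4%, 60.0% and 96.9%, and for inhibitor against DMSO 5.95%, 59.2% and 97.0%. False calls per simulation averaged 0.7, 0.4 and 11.6 for R848 against DMSO, 0, 16.7 and 0.3 for inhibitor against R848, and 6.5, 30.3 and 25.2 for inhibitor against DMSO. Simulated lists with no shift were called in 74 of 388 cases (19.1%) by camera at the preset correlation and in 2 (0.515%) with an estimated correlation, which recovered 18 of 20 lists shifted 2-fold against 20 of 20. A simulated share of 50% came back as 50.5%.

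The alternatives tried were the number as a fixed block, as a random block (statmod 1.5.0, consensus correlation 0.531), and the 6 numbers present in all groups with the block. Others were quantile normalization, 1 median of the genes tested for every array, log2 offsets of 1 and 50, no filter, the upper 40% of genes, the mean of a gene's probe sets, every probe set on its own, trended and robust variances, array weights, the 2 compared groups alone, an adjusted p of 0.01, 1.5-fold and 4-fold minimum changes, each array left out in turn, and for lists an estimated correlation and the rotation test fry. Alternatives added after the data were examined were scaling to the hybridization spikes (control probe sets for bacterial and phage transcripts added in fixed amounts), leaving number 4 or number 9 out of every group, 2 further settings of camera, a bootstrap of whole numbers with all their arrays for the share left, and simulated unchanged groups fitted with the block for the overlap. Figures were drawn with matplotlib 3.10.9.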

Results

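Primary human monocytes were enriched from the blood of healthy donors and exposed for 1 h to R848, a small-molecule agonist of the endosomal receptors TLR7 and TLR8, at 0.5 ug/ml. Some cultures received PF-06426779, a compound known here by its code name and used as an inhibitor of the kinase IRAK4, at 1 uM for 30 min before R848. IRAK4 is a kinase of the MYD88 complex, which carries the signal of most Toll-like receptors. Transcript levels were measured on 24 Affymetrix arrays with 54675 probe sets each. The DMSO group held 8 arrays, the R848 group 9 and the R848 + PF-06426779 group 7. The deposited signal had a median of 100 on every array, and the number of arrays limits the precision of each value. All changes are given on the scale of log2(signal + 20), which understates the change of dim genes, and 11865 genes were tested. The titles number the arrays within each group, and arrays with the same number in different groups formed 8 pairs for R848 against DMSO, 7 for inhibitor against R848 and 6 for inhibitor against DMSO.

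The first comparison asked which transcripts R848 alone changed within 1 h. IFNB1, which encodes interferon beta, rose by 8.62 ± 0.47 on the log2 scale (SE, 9 R848 and 8 DMSO arrays, adjusted p = 6.1e-13), from a mean of 6.31 ± 1.33 to 14.93 ± 0.80 (SD). IL12B, the shared subunit of interleukins 12 and 23, rose by 7.12 ± 0.44 (adjusted p = 8.06e-12), and the inflammatory cytokine IL6 rose by 4.06 ± 0.25 (adjusted p = 8.06e-12). TNF rose by 2.12 ± 0.16 (adjusted p = 2.14e-10). All 4 genes were higher with R848 in 8 of 8 same-numbered pairs. The myeloid transcription factor CEBPA fell by 2.76 ± 0.32 (adjusted p = 4.78e-07) and was lower in 8 of 8 pairs.

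Among the 26 inflammatory cytokine genes tested, 20 rose, none fell and 6 did not pass the threshold, and 20 rose adjusted over the list alone. The median change was 1.80, and the list shifted against the other genes with camera (adjusted p = 1.41e-23). IL23A, which pairs with IL12B to form interleukin 23, rose by 4.83 ± 0.34, IL36G by 4.54 ± 0.31 and IL1A by 2.12 ± 0.14. IL1B, whose mean signal was already 14.92 in DMSO, rose by 0.80 ± 0.16 (adjusted p = 6.68e-04). The anti-inflammatory cytokine IL10 was 0.71 ± 0.49 higher and did not pass (adjusted p = 0.346). Of 21 chemokine genes, 16 rose and none fell, with the same counts adjusted over the list alone (median 1.31, camera adjusted p = 7.94e-13). CCL5 rose by 3.44 ± 0.26, CCL20 by 3.27 ± 0.24, CXCL10 by 2.36 ± 0.52 and the neutrophil attractant CXCL8 by 0.86 ± 0.20. CCL4 rose by 1.31 ± 0.17. In the group of 13 type I and III interferon genes, 13 rose, over all genes and adjusted over the list alone (median 5.36, camera adjusted p = 4.11e-23). The filter had kept 13 of the 17 interferon genes on the array. Genes as dim in DMSO as IFNA14, IFNA17 and IFNA4 could pass it only through the stimulated arrays, so the count was partly fixed by the filter. Without the filter, camera gave an adjusted p of 1.06e-28. IFNA2 rose by 6.46 ± 0.52 and IFNA4 by 6.36 ± 0.60, but the IFNA genes are near-identical paralogs, so which member each probe set measured is uncertain. The list of genes linked to the transcription factor IRF5 in the literature, which shares all its members with these 3 lists, had 11 of 12 members that rose, also adjusted over the list alone (median 3.75, camera adjusted p = 6.14e-22).

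**Figure D1:**
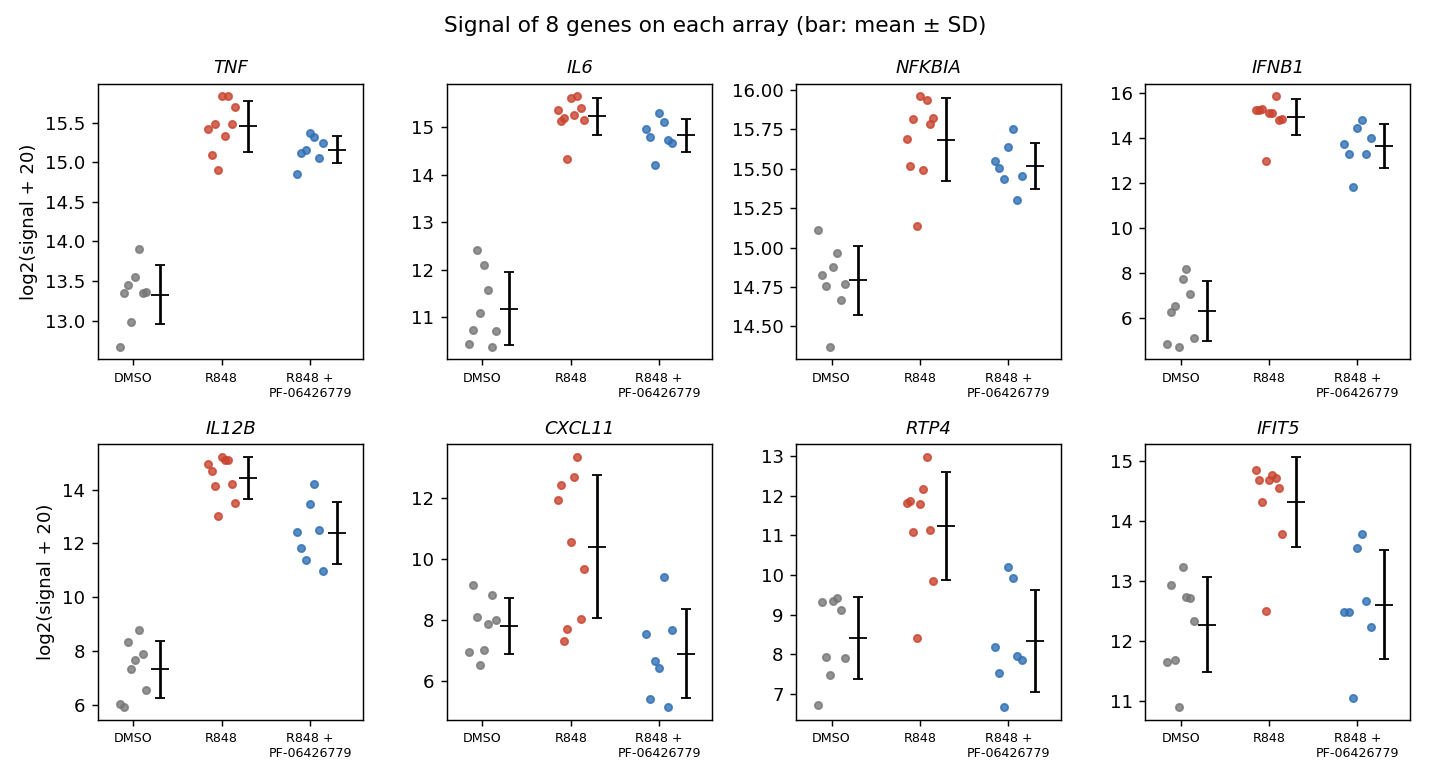
Signal of 8 genes on each array as log2(signal + 20), with 1 point per array and a bar for the mean ± SD of the DMSO (8 arrays), R848 (9) and R848 + PF-06426779 (7) groups. In the order of the groups, means were 13.33, 15.45 and 15.16 for TNF, 11.17, 15.23 and 14.83 for IL6, 6.31, 14.93 and 13.62 for IFNB1, and 8.41, 11.23 and 8.33 for RTP4.

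NF-kB target and feedback genes rose in 32 of 36 cases and fell in none, with 33 risen adjusted over the list alone (median 0.96, camera adjusted p = 8.33e-28). Quantile normalization gave 26 risen, and scaling of the arrays to their hybridization spikes 11 risen and 1 fallen. The inhibitor of NF-kB NFKBIA rose by 0.89 ± 0.13 (adjusted p = 1.55e-05), the ubiquitin-editing enzyme TNFAIP3 by 0.89 ± 0.15, TNIP3 by 4.08 ± 0.27 and the receptor CD40 by 4.23 ± 0.34. Of 31 immediate-early genes, 22 rose and none fell, or 23 adjusted over the list alone (median 0.84, camera adjusted p = 1.30e-18), among them GADD45B (2.29 ± 0.16) and PPP1R15A (1.91 ± 0.16). Quantile normalization gave 17 risen in this list, and spike scaling 12 risen and 2 fallen. The cytokine, chemokine, interferon, IRF5-linked, NF-kB and immediate-early lists, 6 in all, also passed with an estimated correlation, where their adjusted p ranged from 1.47e-04 to 0.0132. MAPK phosphatase and feedback genes gave 8 risen, 1 fallen and 11 not past the threshold of 20 tested, or 9 and 1 adjusted over the list alone and 11 and 4 with the number as a block. The MAPK list shifted (median 0.48, or −0.13 under spike scaling, camera adjusted p = 1.55e-04). That call was lost with an estimated correlation (adjusted p = 0.119 with an estimated correlation). DUSP2 rose by 1.69 ± 0.24 and RGS1 by 2.10 ± 0.19, and DUSP7, which inactivates ERK, fell by 1.91 and was named after its values were seen. The 15 JAK-STAT feedback genes split, with 5 risen and 4 fallen, or 6 and 4 adjusted over the list alone (median 0.27, or −0.34 under spike scaling, camera adjusted p = 0.145). SOCS1 rose by 2.32 ± 0.40 and PIM3 by 0.79 ± 0.15, whereas SOCS6 fell by 1.85 ± 0.27 and SOCS5 by 1.33 ± 0.17.

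Of 44 interferon-stimulated genes, 14 rose, none fell and 30 did not pass, with the same counts adjusted over the list alone (median 0.34, or −0.27 under spike scaling, camera adjusted p = 3.50e-06). This list call was lost with an estimated correlation (adjusted p = 0.381 with an estimated correlation). IFIT5 rose by 2.04 ± 0.37, LAMP3 by 1.98 ± 0.37, the antiviral OASL by 1.39 ± 0.20, and RSAD2 by 1.22 ± 0.33. Among 32 TLR7/8 signalling components, 3 rose (IRAK2 by 0.75 ± 0.16, TBK1 by 0.66 ± 0.13 and MAPK8 by 0.47 ± 0.14, or −0.14 under spike scaling) and 3 fell (TRAF6 by 1.07 ± 0.22, TIRAP by 0.95 ± 0.25 and PELI3, named after its values were seen, by 1.51). The counts were the same adjusted over the list alone and 7 and 6 with the block, but 8 and 3 with 1 median of the genes tested and 0 and 14 under spike scaling. The list did not shift (median 0.02, or −0.06 under quantile normalization and −0.59 under spike scaling, mean −0.06, camera direction up, adjusted p = 0.547). IRF5 was 1.09 ± 0.42 lower (adjusted p = 0.0628) and TLR7 0.80 ± 0.36 higher (adjusted p = 0.114), each in 8 of 8 pairs. With the number as a block IRF5 passed at an adjusted p of 8.67e-06 and TLR7 at 8.70e-05, while TLR8 differed by 0.05 ± 0.32 (adjusted p = 0.938). Of 23 other pattern receptors, 8 rose and 3 fell, or 8 and 4 adjusted over the list alone (median 0.09, or −0.52 under spike scaling, camera adjusted p = 0.0376). That shift was lost with an estimated correlation (adjusted p = 0.361 with an estimated correlation), under quantile normalization (adjusted p = 0.355) and with 1 median of the genes tested (adjusted p = 0.082). The inflammasome sensor NLRP3 rose by 2.09 ± 0.20, CLEC4D by 1.68 ± 0.32 and AIM2 by 1.58 ± 0.38, and TLR1 fell by 1.28 ± 0.24. Apoptosis regulators gave 7 risen and 1 fallen of 20, also adjusted over the list alone (median 0.01, or −0.60 under spike scaling, camera adjusted p = 0.056). Quantile normalization gave 4 and 1, and spike scaling 1 and 8. PMAIP1 rose by 3.10 ± 0.28 and MCL1 by 0.62 ± 0.15, and the pro-apoptotic BMF fell by 1.38 ± 0.28. Heat shock and stress genes gave 6 risen of 20, also adjusted over the list alone (camera adjusted p = 0.0608), among them HSPA6 (1.35 ± 0.31) and DNAJA1 (1.15 ± 0.20). Their median of 0.07 became −0.02 under quantile normalization and −0.54 under spike scaling.

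Cytosolic ribosomal protein genes rose in 33 of 33 cases, over all genes and adjusted over the list alone, by a median of 0.50 (camera adjusted p = 1.07e-13), but their median was −0.01 under quantile normalization (adjusted p = 0.973) and −0.11 under spike scaling, with none past the threshold in limma under either. With an estimated correlation the ribosomal list also lost its call (adjusted p = 0.257 with an estimated correlation). Of 20 glycolysis genes, 7 rose, also adjusted over the list alone and 11 with the block (median 0.39, camera adjusted p = 3.16e-04). Among them were PFKFB3 (0.84 ± 0.15), SLC2A3 (0.80 ± 0.19) and GAPDH (0.52 ± 0.15, or −0.09 under spike scaling). The glycolysis median became −0.01 under quantile normalization, with 2 risen (adjusted p = 0.22), and −0.22 under spike scaling, and the call was lost with an estimated correlation (adjusted p = 0.103 with an estimated correlation). Monocyte markers gave 3 risen (CD14 by 0.60 ± 0.16, or −0.01 under spike scaling, S100A8 by 0.49 ± 0.14, or −0.12 there and −0.01 under quantile normalization, and CLEC12A by 0.86 ± 0.24) and 1 fallen (the chemokine receptor CCR2, by 2.14 ± 0.57) of 17. The counts were the same adjusted over the list alone and 6 and 2 with the block. Their median of 0.29 (camera adjusted p = 0.0189) turned to −0.11 under quantile normalization (adjusted p = 0.881) and −0.32 under spike scaling, and the call was lost with an estimated correlation (adjusted p = 0.257 with an estimated correlation).

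Markers of other blood cells were tested in the same way, and the 5 lists had medians above 0 that turned below 0 under spike scaling (−0.33 to −0.60). None of 9 T cell markers passed in limma, over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05, median 0.24, camera adjusted p = 0.22), while 2 were higher with the block. Of 13 NK cell markers 1 rose, NCR1 by 1.13 ± 0.35, also adjusted over the list alone (median 0.25, camera adjusted p = 0.103). The NK cell list shifted under quantile normalization (adjusted p = 0.0229) and not as deposited with an estimated correlation (adjusted p = 0.597 with an estimated correlation). No B cell or plasmacytoid dendritic cell marker of 12 passed (median 0.01, camera adjusted p = 0.665), and no platelet or red cell marker of 12 passed (median 0.28, camera adjusted p = 0.34). Both counts were also 0 adjusted over the list alone and at limma's unadjusted p under 0.05. With the block 2 platelet or red cell markers were higher and no B cell marker was called. Granulocyte markers gave 2 risen of 16, FFAR2 by 2.96 ± 0.24 and LTF by 0.89 ± 0.28, also adjusted over the list alone. The block gave 4 higher and 2 lower, and the list shifted (median 0.27, camera adjusted p = 0.0376). That shift was lost with an estimated correlation (adjusted p = 0.259 with an estimated correlation), with the block (adjusted p = 0.0674) and with 1 median of the genes tested (adjusted p = 0.082).

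With limma, 2704 of 11865 genes passed an adjusted p of 0.05, 1092 higher and 1612 lower with R848, and 1048 of them changed at least 2-fold (476 up, 572 down). With the number as a block 4778 genes passed (1791 higher, 2987 lower), and all 2704 were among them. The largest falls were those of CENPBD1P (−3.12 ± 0.27), GTF2H2B (−3.05 ± 0.38) and PHF23 (−2.97 ± 0.27), each lower in 8 of 8 pairs. The balance of directions depended on the scaling. Genes higher with R848 made up 40.4% of calls as deposited, 37.9% under quantile normalization, 68.4% with 1 median of the genes tested (2221 higher, 1026 lower) and 4.97% with arrays scaled to the hybridization spikes (326 higher, 6231 lower). The median of all genes was −0.06 as deposited, −0.06, 0.17 and −0.67 in the same order, so a list is best read against it. The spikes themselves were 0.61 higher on R848 than on DMSO arrays (exact permutation p = 0.0079, adjusted p = 0.0822 over 15 comparisons). Less labelled sample per array could give this, so the many falls under spike scaling need not be falls in the cells. Under spike scaling only the interferon (4.75), IRF5-linked (3.14), cytokine (1.19), chemokine (0.70), NF-kB (0.35) and immediate-early (0.23) lists kept medians above 0, and the other 15 lay below 0 but above −0.67. Counts risen and fallen under spike scaling were 15 and 0 for cytokines, 10 and 1 for chemokines, 6 and 0 for interferon-stimulated genes, 3 and 2 for MAPK, 1 and 6 for JAK-STAT, 4 and 6 for pattern receptors, 1 and 5 for heat shock, 0 and 4 for glycolysis and 0 and 3 for monocyte genes. With 1 median of the genes tested, 11 glycolysis genes and 11 monocyte markers rose. The smaller rises of IL1B, CXCL8, NFKBIA, TNFAIP3, IRAK2, TBK1, RSAD2, HSPA6, MCL1, PFKFB3, SLC2A3, CLEC12A, LTF and NCR1 no longer passed under spike scaling. The rises of CXCL8, IRAK2, MAPK8, MCL1, SLC2A3, GAPDH and CD14 did not pass under quantile normalization. NCR1 also did not pass without DMSO replicate 3 (adjusted p = 0.0514).

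The second comparison asked what the inhibitor changed in R848-stimulated cells. In limma without the number 39 genes were lower and 6 higher with the inhibitor, and with the number as a block 150 were lower and 112 higher. Most of the lower genes had risen with R848 (38 of 39, or 141 of 150 with the block). CXCL11, a chemokine induced by interferons, fell by 3.53 ± 0.79 against R848 alone (SE, 7 inhibitor and 9 R848 arrays, adjusted p = 0.0386). With R848, CXCL11 was high in replicates 2 and 7 (12.43 and 13.36), which have no inhibitor array. It was low in replicates 3, 4 and 8 (7.31, 7.69 and 8.02). The fall over all arrays therefore exceeds the mean fall within pairs. RTP4, an interferon-induced chaperone, fell by 2.91 ± 0.57 (adjusted p = 0.011). BHLHE22, a transcription factor, fell by 3.003 ± 0.32 (adjusted p = 5.66e-06), the cortisone reductase HSD11B1 by 2.13 ± 0.22 (adjusted p = 3.58e-06) and IL12B by 2.04 ± 0.46 (adjusted p = 0.0413). These 5 genes were lower in 7 of 7 same-numbered pairs. TNF was 0.29 ± 0.17 lower (6 of 7 pairs, adjusted p = 0.999) and IL6 0.41 ± 0.26 lower (7 of 7 pairs, adjusted p = 0.999), and neither passed with the block. CACNA1A (−2.34 ± 0.36), ST7-AS1 (−2.18 ± 0.31), RMI2 (−2.01 ± 0.32), FSD1L (−2.004 ± 0.26) and CSRP2 (−1.98 ± 0.35) completed the 10 largest falls.

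Of 44 interferon-stimulated genes, 1 fell, IFIT5 by 1.71 ± 0.38 (adjusted p = 0.0381), while 11 fell adjusted over the list alone and 12 with the number as a block. OASL was 0.75 ± 0.21 lower (block adjusted p = 0.00281), RSAD2 1.11 ± 0.34 lower (block adjusted p = 0.00131) and the RNA sensor IFIH1 1.02 ± 0.27 lower (block adjusted p = 0.00367), each in 7 of 7 pairs. The list median was −0.68 (camera adjusted p = 5.73e-27), a call lost with an estimated correlation (adjusted p = 0.123 with an estimated correlation). Among 26 inflammatory cytokines only IL12B fell over all genes, 3 fell adjusted over the list alone, and the block gave 5 lower and 1 higher (median −0.26, camera adjusted p = 2.91e-05). With an estimated correlation that list lost its call (adjusted p = 0.123 with an estimated correlation). IL23A was 0.86 ± 0.36 lower (block adjusted p = 0.0317) and TNFSF9 1.15 ± 0.27 lower (adjusted p = 0.0653, block adjusted p = 0.00872). IL10 was 1.45 ± 0.51 higher, in 7 of 7 pairs (adjusted p = 0.412, block adjusted p = 0.0175), and IL1B was 0.16 ± 0.17 lower. Of 21 chemokines CXCL11 fell, 5 fell adjusted over the list alone, and the block gave 3 lower and 1 higher. CXCL10 was 1.63 ± 0.54 lower (adjusted p = 0.356, block adjusted p = 0.00796), whereas CCL20 was 0.07 ± 0.25, CXCL8 0.12 ± 0.21 and CCL4 0.20 ± 0.18 lower. The chemokine median of −0.08, with a mean of −0.35, became 0.03 under quantile normalization and under spike scaling (camera adjusted p = 9.37e-04, or 0.0566 under quantile normalization). The chemokine call was also lost with an estimated correlation (adjusted p = 0.259 with an estimated correlation).

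None of 13 interferon genes fell in limma, over all genes or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05. The block called IFNB1, which was 1.31 ± 0.49 lower (adjusted p = 0.465, block adjusted p = 0.0417) in 7 of 7 pairs. The interferon median was −1.09 (camera adjusted p = 4.30e-10), a call lost with an estimated correlation (adjusted p = 0.238 with an estimated correlation). In the IRF5-linked list IL12B fell, 5 members fell and 1 rose adjusted over the list alone, and the block gave 4 and 1. Its median was −0.97 (camera adjusted p = 6.62e-10), its adjusted p was 0.0555 with an estimated correlation, and it was 0.0292 with the block and an estimated correlation together. Of 36 NF-kB genes, CD40 fell by 1.95 ± 0.35 (adjusted p = 0.0052), also the only one adjusted over the list alone, and the block added TNIP3 (−0.76 ± 0.28, block adjusted p = 0.0204). NFKBIA was 0.16 ± 0.14 and TNFAIP3 0.11 ± 0.16 lower. The NF-kB median of −0.10 became 0.02 under spike scaling (camera adjusted p = 3.43e-04, or 0.561 under quantile normalization), and the call was lost with an estimated correlation (adjusted p = 0.688 with an estimated correlation).

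No pattern receptor of 23 passed over all genes in limma (3 were lower at an unadjusted p under 0.05), and 1 fell adjusted over the list alone. The block gave 3 lower, AIM2 (−1.58 ± 0.40, block adjusted p = 0.00682), CLEC4D (−0.84 ± 0.33, block adjusted p = 0.0381) and MEFV (−0.79 ± 0.35, block adjusted p = 0.0059). Their median of −0.08 became 0.03 under spike scaling (camera adjusted p = 0.00287), and the call was lost with an estimated correlation (adjusted p = 0.266 with an estimated correlation). No ribosomal protein gene of 33 passed in limma, also adjusted over the list alone and at an unadjusted p under 0.05, and their median of −0.13 (camera adjusted p = 4.47e-06) became −0.01 under quantile normalization (adjusted p = 0.787). The ribosomal call was also lost with an estimated correlation (adjusted p = 0.75 with an estimated correlation). No immediate-early gene of 31 passed, also adjusted over the list alone (1 higher and 1 lower at limma's unadjusted p under 0.05). Their median of −0.07 became 0.01 under quantile normalization and 0.04 under spike scaling (camera adjusted p = 0.0916, or 0.00411 with the block). That call with the block was lost with an estimated correlation (adjusted p = 0.45 with an estimated correlation). Heat shock and stress genes had no call over all genes and 1 adjusted over the list alone or at limma's unadjusted p under 0.05, HSPA6 at −1.30 ± 0.32 (block adjusted p = 0.00296). Their median of −0.03 became 0.08 under spike scaling (camera adjusted p = 0.26, or 0.047 with the block). The latter was also lost with an estimated correlation (adjusted p = 0.542 with an estimated correlation). Camera called no shift in MAPK feedback (median 0.12, adjusted p = 0.67), JAK-STAT feedback (0.05, 0.701), TLR7/8 signalling (−0.01, 0.472), apoptosis (−0.04, 0.418) or glycolysis genes (−0.03, 0.322). The last 4 medians crossed 0 under at least 1 other scaling. No member of these lists passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 1 higher MAPK gene, 1 higher JAK-STAT gene, 1 lower apoptosis gene and 0 in the other lists. Camera also called no shift in monocyte (−0.03, 0.406), T cell (0.08, 0.512), NK cell (0.10, 0.778), B cell and plasmacytoid dendritic cell (−0.04, 0.472) and platelet and red cell markers (0.23, 0.391). The monocyte and B cell medians crossed 0 under at least 1 other scaling. None of these markers passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. The block called no member of these 10 lists. Granulocyte markers had no call over all genes, 1 fallen adjusted over the list alone and 1 risen with the block, MMP9 (0.61 ± 0.38, block adjusted p = 0.0321). Their median of 0.05 became −0.01 under quantile normalization, their mean was −0.01, and camera's direction was down (adjusted p = 0.472). At limma's unadjusted p under 0.05, 1 granulocyte marker was lower.

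With limma 45 genes passed, 39 lower and 6 higher with the inhibitor, and 39 of the 45 changed at least 2-fold (36 down, 3 up). The block called 262 genes (112 higher, 150 lower), which included all 45, and 85 of them changed at least 2-fold. The 6 genes that rose were SOWAHC (1.37 ± 0.28), ARRDC3 (1.12 ± 0.25), LOC105377276 (1.06 ± 0.21), KCNJ15 (0.99 ± 0.22), SNX33 (0.77 ± 0.16) and CASTOR1 (0.74 ± 0.16), with adjusted p from 0.0109 to 0.0396. All were higher in 7 of 7 pairs except ARRDC3 (6 of 7). Of 18 named genes called here, 10 kept their calls under every alternative run for named genes, at an adjusted p of 0.05. An adjusted p of 0.01, other minimum changes and every probe set on its own were not applied to named genes. The stricter filter by mean was applied only to the genes it kept. Leaving out 1 array ended the call of IL12B for 15 of the 24 arrays (highest adjusted p = 0.148), of ARRDC3 and CASTOR1 for 13 each (0.126 and 0.0837), and of CXCL11, IFIT5 and KCNJ15 for 12 each (0.126, 0.11 and 0.121). SNX33 lost its call without inhibitor replicate 3 (adjusted p = 0.0539) or 9 (0.0689), and SOWAHC without inhibitor replicate 8 (0.0614) or 9 (0.0689). Without R848 replicate 4 the count rose from 45 to 73.

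The third comparison asked what remained of the R848 response with the inhibitor, against DMSO. IFNB1 was still 7.31 ± 0.50 above DMSO (SE, 7 inhibitor and 8 DMSO arrays, adjusted p = 1.84e-10), IL12B 5.08 ± 0.47 (adjusted p = 2.58e-08), IL6 3.66 ± 0.27 (adjusted p = 8.15e-10) and TNF 1.83 ± 0.17 (adjusted p = 2.77e-08). All 4 were higher in 6 of 6 same-numbered pairs. CXCL11 differed from DMSO by −0.91 ± 0.81 (adjusted p = 0.539), RTP4 by −0.08 ± 0.59 (adjusted p = 0.954) and CACNA1A by 0.15 ± 0.37 (adjusted p = 0.849), each higher in 3 of 6 pairs. For CXCL11 the highest DMSO values were those of replicates 2 and 7 (9.14 and 8.82), which have no inhibitor array. IL10 rose by 2.16 ± 0.53 (adjusted p = 0.00665) in 6 of 6 pairs. CEBPA fell by 2.39 ± 0.34 (adjusted p = 2.73e-05).

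Of 26 cytokine genes 20 rose, or 21 adjusted over the list alone (median 1.73, camera adjusted p = 1.91e-26), with IL23A at 3.97 ± 0.37 and IL1B at 0.64 ± 0.17. Chemokines gave 10 risen of 21, or 13 adjusted over the list alone and 16 with the block (median 0.75, camera adjusted p = 2.71e-11). CCL20 rose by 3.19 ± 0.26 and CCL5 by 2.30 ± 0.28, and CXCL10 was 0.73 ± 0.55 higher (adjusted p = 0.457, block adjusted p = 0.015). NF-kB genes gave 28 risen of 36, or 33 adjusted over the list alone (median 0.88, camera adjusted p = 3.18e-31), with NFKBIA at 0.73 ± 0.14 and TNFAIP3 at 0.78 ± 0.16. Immediate-early genes gave 21 risen of 31, or 22 adjusted over the list alone (median 0.75, camera adjusted p = 8.03e-22). All 13 interferon genes rose, also adjusted over the list alone (median 4.21, camera adjusted p = 4.13e-23), as did 11 of 12 IRF5-linked genes (median 2.98, camera adjusted p = 4.13e-23). The filter partly fixed this interferon count too. MAPK feedback genes gave 10 risen and 1 fallen (DUSP7) of 20, also adjusted over the list alone (median 0.55, camera adjusted p = 2.06e-06), with SPRY1 at 1.68 ± 0.38 and RGS16 at 1.65 ± 0.39. These 7 lists also passed with an estimated correlation, and the MAPK list had the highest value (adjusted p = 0.0464 with an estimated correlation), which was 0.0884 with the block added.

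Interferon-stimulated genes gave 3 risen of 44, OASL by 0.65 ± 0.21, GBP2 by 0.59 ± 0.16 and IRF1, named after its values were seen, by 0.71, and 1 risen adjusted over the list alone. The block gave 7 higher and 2 lower, and the list did not shift (median −0.18, camera adjusted p = 0.901). Under spike scaling its median was −0.67, with 0 higher and 12 lower. JAK-STAT feedback genes gave 4 risen and 3 fallen of 15, or 8 and 3 adjusted over the list alone (median 0.45, or −0.05 under spike scaling, camera adjusted p = 0.089). SOCS1 rose by 1.71 ± 0.43, and SOCS6 fell by 1.35 ± 0.29. TLR7/8 signalling components gave 2 risen (IRAK2 and TBK1) and 2 fallen (TRAF6 and PELI3) of 32, also adjusted over the list alone, and the block gave 4 and 4. Their list did not shift (median −0.02, or 0.15 with 1 median of the genes tested, camera direction up, adjusted p = 0.881). Pattern receptors gave 2 risen (CLEC4E and NLRP3) and 2 fallen (TLR1 and, named after its values were seen, NLRC4) of 23, or 5 and 2 adjusted over the list alone and 6 and 3 with the block. The receptor list did not shift (median 0.07, or −0.01 under quantile normalization and −0.43 under spike scaling, camera adjusted p = 0.289). Apoptosis regulators gave 4 risen and 1 fallen of 20, or 5 and 1 adjusted over the list alone. PMAIP1 rose by 2.38 ± 0.30 and BMF fell by 1.14 ± 0.30, and the list did not shift (median 0.12, or −0.38 under spike scaling, camera adjusted p = 0.0663). Heat shock genes gave 3 risen of 20, also adjusted over the list alone, among them DNAJA1 at 0.77 ± 0.22 (median 0.09, or −0.01 under quantile normalization and −0.41 under spike scaling, camera adjusted p = 0.132). Quantile normalization left 0 risen in this list, and spike scaling 0 risen and 1 fallen. Glycolysis genes gave 2 risen of 20, SLC2A3 (0.75 ± 0.20) and PFKFB3 (0.66 ± 0.16), or 6 adjusted over the list alone and 8 with the block (median 0.35, or −0.15 under spike scaling). Their camera adjusted p of 5.14e-04 was 0.154 under quantile normalization, and the call was lost with an estimated correlation (adjusted p = 0.102 with an estimated correlation).

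Ribosomal protein genes gave 2 risen of 33, RPLP2 (0.45 ± 0.15, or −0.05 under spike scaling) and RPS14 (0.47 ± 0.14, or −0.03), none adjusted over the list alone, 28 at limma's unadjusted p under 0.05, 9 with the block and 29 with 1 median of the genes tested. Their median of 0.37 became −0.04 under quantile normalization and −0.13 under spike scaling. Their camera adjusted p of 5.14e-10 was 0.871 under quantile normalization, and the call was lost with an estimated correlation (adjusted p = 0.322 with an estimated correlation). No monocyte marker of 17 passed in limma, over all genes or adjusted over the list alone (4 higher and 1 lower at an unadjusted p under 0.05), while the block gave 3 higher and 2 lower. The monocyte median of 0.32 became −0.07 under quantile normalization and −0.18 under spike scaling. The monocyte adjusted p of 0.0329 was 0.0821 with the block and 0.871 under quantile normalization, and the call was lost with an estimated correlation (adjusted p = 0.29 with an estimated correlation). Granulocyte markers gave 2 risen of 16, FFAR2 (1.94 ± 0.26) and MMP8 (0.85 ± 0.23), also adjusted over the list alone. The granulocyte list shifted (median 0.25, or −0.24 under spike scaling, camera adjusted p = 0.0329, or 0.0623 with the block and 0.0671 with 1 median of the genes tested). That call was lost with an estimated correlation (adjusted p = 0.248 with an estimated correlation). No T cell (median 0.37, camera adjusted p = 0.0875, or 0.0316 under quantile normalization), NK cell (0.35, 0.0525, or 0.00869 under quantile normalization), B cell and plasmacytoid dendritic cell (−0.09, mean −0.02, camera direction up, 0.964) or platelet and red cell marker (0.46, 0.0912, or 0.0363 with the block) passed in limma, over all genes or adjusted over the list alone. With an estimated correlation no shift was called in the T cell (adjusted p = 0.198 with an estimated correlation), NK cell (0.518) or, with the block, platelet list (0.241). At an unadjusted p under 0.05 there were 1 higher T cell marker, 1 higher NK cell marker, 1 lower B cell marker and 0 platelet or red cell markers. The block called 1 T cell marker and 1 platelet or red cell marker. The medians of the T cell (−0.13), NK cell (−0.15) and platelet (−0.04) lists lay below 0 under spike scaling, while that of the B cell list was 0.01 under quantile normalization.

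Against DMSO, limma called 1391 genes with the inhibitor, 633 higher and 758 lower, and 640 of them changed at least 2-fold (356 up, 284 down). The block called 2932 (1205 higher, 1727 lower), which kept 1388 of the 1391. Genes that were higher made up 45.5% of calls as deposited, 40.5% under quantile normalization, 70.6% with 1 median of the genes tested (1384 higher, 575 lower) and 5.48% under spike scaling (217 higher, 3740 lower), where the median of all genes was −0.52. Counts risen and fallen under spike scaling were 16 and 1 for cytokines, 7 and 0 for chemokines, 9 and 0 for NF-kB, 9 and 0 for immediate-early, 4 and 1 for MAPK, 1 and 4 for JAK-STAT, 0 and 10 for TLR7/8, 1 and 5 for pattern receptor and 1 and 3 for apoptosis genes. With 1 median of the genes tested they were 7 and 2 for JAK-STAT, 5 and 1 for TLR7/8, 6 and 2 for pattern receptor, 7 and 0 for glycolysis and 5 and 0 for monocyte genes. The spikes were 0.50 higher than on DMSO arrays (exact permutation p = 0.0193, adjusted p = 0.0822 over 15 comparisons). Here too, the many falls under spike scaling need not be falls in the cells. The rises of CXCL8, IL1B, GBP2, OASL, IRAK2, MCL1, DNAJA1, PFKFB3, SLC2A3, RPLP2 and RPS14 did not pass under quantile normalization or under spike scaling. Those of NFKBIA, TNFAIP3, TBK1, CLEC4E, SPRY1 and MMP8 did not pass under spike scaling alone, and TRAF6 did not pass without number 9. Leaving out 1 array ended the call of RPLP2 for 18 of the 24 arrays (highest adjusted p = 0.0996), of OASL for 17 (0.103), of RPS14 for 9 (0.0705) and of MCL1 for 9 (0.0681). The call of CXCL8 ended without DMSO replicate 7 (adjusted p = 0.0514) and that of DNAJA1 without inhibitor replicate 6 (0.0554).

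The last question was how much of each response was left with the inhibitor, taken per gene as the change from DMSO with R848 and inhibitor over the change with R848 alone. Both changes are on the log2 scale, so a share is not the percentage of signal kept. It also depends on the size of the R848 change. The median change of inhibitor against R848 was −1.09 for the 13 interferons and −0.68 for the 44 interferon-stimulated genes. Over the 476 genes that R848 raised at least 2-fold, the median share left was 77.5% (95% bootstrap interval 69.5 to 86.1), with 86 genes below 50% and 79 over 100%. Over the 572 genes that fell at least 2-fold it was 74.4% (56.0 to 93.3). The 12 interferon-stimulated genes in this set kept a median of 20.7% (−27.7 to 63.6), or 35.7% with the 6 numbers present in all groups and the block, and 10 of the 12 lay below 50%, with IFIT5 at 16.4% (Fieller 95% interval −29.1 to 50.4). NF-kB genes kept 88.8% (77.0 to 97.6, 16 genes), immediate-early genes 85.9% (78.6 to 98.6, 13 genes), chemokines 85.0% (61.4 to 98.9, 11 genes) and cytokines 84.6% (77.1 to 94.3, 18 genes). The chemokine median hides a split, since 4 of the 11 lay below 50%, CXCL10 at 30.8%, CCL8, named after its values were seen, at 20.8%, CXCL9 at 19.1% and CXCL11 at −34.9%, and 3 over 100%. The CXCL11 share includes DMSO and R848 arrays of numbers 2 and 7, which were high for it and have no inhibitor array. Below 50% lay 1 cytokine and no NF-kB or immediate-early gene. IRF5-linked genes kept 82.7% (69.7 to 92.4, 10 genes), interferons 80.6% (58.1 to 103, 13 genes), MAPK feedback genes 101% (76.5 to 120, 5 genes) and pattern receptors 50.3% (24.04 to 82.4, 5 genes). Drawing whole numbers, which keeps same-numbered arrays together, gave 68.3 to 88.4 for interferons and 1.22 to 37.7 for interferon-stimulated genes. It gave 84.8 to 119 for MAPK feedback genes and 70.9 to 82.7 for all genes up. The interferon interval then lay below 100%. In DMSO, IFNA14 and IFNA4 lay near the floor of the log2 scale (4.55 without replicate 5 and 4.61 without replicate 6). The offset of 20 therefore affects the shares of such dim interferons. Among single genes, IL6 kept 90.0% (77.7 to 103), TNF 86.2% (71.4 to 103), IFNB1 84.8% (74.2 to 96.2), IL12B 71.4% (59.6 to 83.9), CD40 53.8% and BHLHE22 49.5%. On R848 arrays TNF lay at 14.90 or more, IL6 at 14.32 or more and IFNB1 at 12.96 or more. The NF-kB genes in the share had a median level of 14.09 over all arrays. Compression of bright signals could raise such shares, and it was not tested for these genes.

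**Figure D2:**
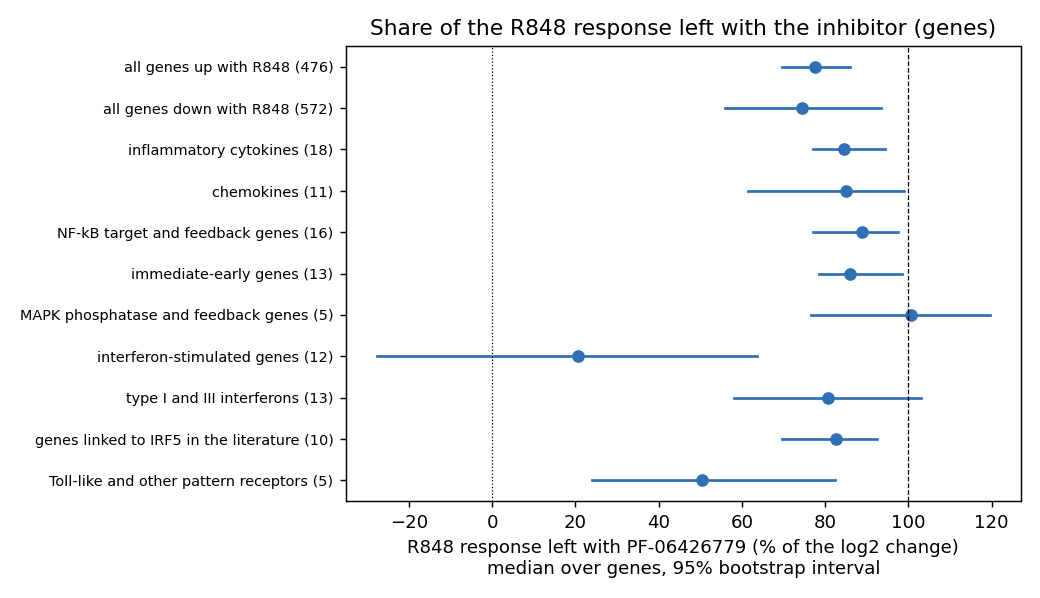
Median share of the R848 response left with the inhibitor (% of the log2 change) for each gene list, with its 95% bootstrap interval and the number of genes in brackets, and lines at 0 and 100%. The bootstrap drew arrays within groups and did not keep same-numbered arrays together. Draws that kept them together gave 1.22 to 37.7 for interferon-stimulated genes and 68.3 to 88.4 for interferons. Interferon-stimulated genes lie lowest at 20.7% (35.7% with the 6 numbers present in all groups and the block), and NF-kB genes lie at 88.8%.

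The interferon-stimulated share lay 68.1 percentage points below that of the NF-kB genes (difference −68.1, 95% bootstrap interval −110 to −31.6). Its bootstrap p of 0.002 was the smallest the draws can give (adjusted p = 0.008 over 8 comparisons). Pattern receptors differed from the NF-kB genes by −38.5 points (−63.4 to −8.09, bootstrap adjusted p = 0.008), and the other 6 lists did not pass the threshold (lowest adjusted p = 0.469). Draws of whole numbers, which keep same-numbered arrays together and were added after the data were examined, gave −87.9 to −49.99 for interferon-stimulated genes and −52.7 to −18.5 for pattern receptors (adjusted p = 0.008 for each). The lowest adjusted p of the other 6 was then 0.256, for IRF5-linked genes (−6.11, −14.98 to 1.47). Both responses in the ratio share arrays, so genes were also chosen on one part of the arrays and measured on the other. The median over 100 splits was 79.99% for genes up and 78.1% for genes down with the R848 arrays split, 76.9% and 73.5% with the DMSO arrays split, and 78.7% and 76.2% with both split.

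**Figure D3:**
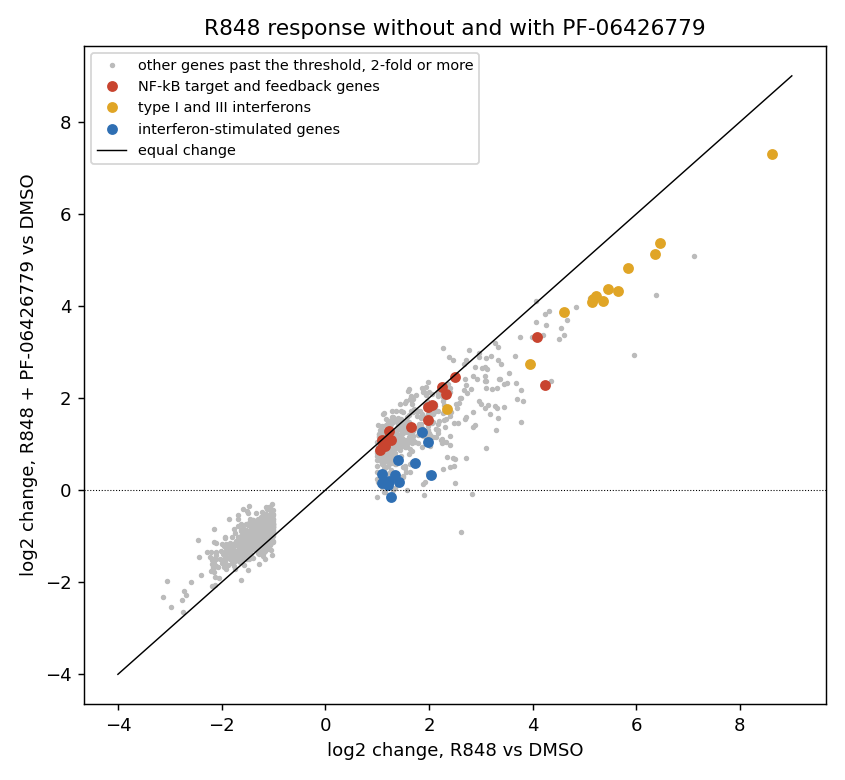
Change against DMSO with R848 and inhibitor (y axis, log2) plotted against the change with R848 alone (x axis, log2) for the 1048 genes that R848 changed at least 2-fold, 1 point per gene, with NF-kB genes, interferons and interferon-stimulated genes coloured and a line of equal change. Most points lie between 0 and the line, with median shares of 77.5% for genes up and 74.4% for genes down.

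Of the 39 genes that fell with the inhibitor, 38 had risen with R848, and the exception was FASTKD3 (−0.76 with the inhibitor, 0.13 ± 0.17 with R848, adjusted p = 0.633), named after its values were seen. Of the 6 that rose, 4 had fallen with R848, SOWAHC, ARRDC3, KCNJ15 and SNX33. Independent lists of these sizes would share 3.59 and 0.815 genes. Simulated unchanged groups that share the R848 arrays gave means of 2.20 and 0.75, with no shared gene in 98% of simulations and a highest count of 182 and 41. These simulations drew residual arrays at random over the numbers, so they lack the correlation of same-numbered arrays. With the R848 arrays split between the comparisons the medians were 3 (0 to 33) and 0 (0 to 3), in fits with fewer arrays. In limma no gene rose in both comparisons (8 at an unadjusted p under 0.05 in both, 4 with the block) and none fell in both (3 and 0). Without R848 replicate 4 the overlaps were 61 and 8, and the second was 1 without inhibitor replicate 3, 8 or 9 and 2 without R848 replicate 2, 3, 7 or 8 or inhibitor replicate 5. With the block 141 of 150 and 88 of 112 overlapped. In 100 simulations of unchanged groups fitted with the block, run after the data were examined, 99% and 98% gave no overlap. The highest overlap was 12 genes in either. At most 57 genes were called for the inhibitor in those simulations, against 262 in the data. An unchanged inhibitor mostly gives few calls, so neither set of simulations shows how much overlap shared arrays give among as many called genes. Across genes, which are not independent replicates, the log2 changes of the comparisons correlated at −0.58, where simulated unchanged groups gave −0.17 (−0.56 to 0.17) and split arrays −0.35. The covariance of −0.112 lay within the range of the same simulations (−0.155 to 0.0266), which lack the correlation of same-numbered arrays.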

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

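The tests of the ribosomal pattern under quantile normalization and against the hybridization spikes were chosen after the result was seen, and the other tests of this part were written down before it.

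With the inhibitor, interferon-stimulated genes kept a smaller share of their R848 response than NF-kB genes, by 68.1 percentage points. Use of the same R848 arrays to choose genes and to measure them is argued against, because with the arrays split the median difference was −58.8 points, and the highest of 100 splits was −40.2. Compression at the level of the interferon-stimulated genes is argued against by other genes of that level that rose with R848, which kept 79.1% (100 genes), or 58.4 points more than the interferon-stimulated genes. The NF-kB genes were brighter (median level 14.09 against 13.26). Genes matched to them were not examined, so compression of the NF-kB share was not tested. The different make-up of the groups is argued against as the whole cause by the 6 numbers present in all groups. There the difference with the block was −50.5 points (35.7% against 86.2%). It was smaller than the 68.1 points over all arrays, so part of the gap depended on which numbers were included. The genes were still those chosen on all arrays. A candidate explanation that remains is biological, that interferon-stimulated genes respond more to the inhibitor at 1 h than NF-kB genes, a hypothesis since the pattern was found and tested on the same data.

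Cytosolic ribosomal protein genes rose together with R848, and the technical explanations tested remain open, that of the spikes only for the rise in signal as such. Under quantile normalization their median lay 0.0503 above that of all genes, against 0.56 as deposited, so a difference in signal distribution between arrays could account for the rise. It lay 0.0298 above the median of 120 other genes of the same level (0.47), so the rise may be one shared by bright genes. The spikes rose by 0.61, from 14.48 ± 0.34 to 15.09 ± 0.44 (SD, 8 and 9 arrays, exact permutation p = 0.0079, adjusted p = 0.0822 over 15 comparisons), which is 0.11 more than the ribosomal genes, as less labelled sample per array could give. Such a shift moves all genes alike and cannot give a rise against other genes. Under spike scaling the ribosomal median was −0.11, and that of all genes −0.67. A change in the cells with R848 was not tested apart from these.

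Chance alone is an unlikely source of the gene counts, since none of the other splits drawn, of the same arrays into groups of the same sizes, gave as many genes. The 1 of 100 or 1 of 64 is the lowest share these draws can give, so chance is not excluded. Splits over all arrays do not keep same-numbered pairs parted, as the real split does. For R848 against DMSO, the real split (1 of 100) gave 2704 genes and the highest other 727, or 1458 among splits that part all 8 same-numbered pairs (1 of 100), with 4778 and 3276 under the block (1 of 100), where the highest other exchanged 1 pair. For inhibitor against R848 the counts were 45 and 1 over all splits, 45 and 1 over splits that part the 7 pairs, and 262 and 5 with the block (2 pairs exchanged), the real split being 1 of 100 each time. For inhibitor against DMSO they were 1391 and 918 (1 of 100), 1391 and 323 over the splits that part the 6 pairs (1 of 64), and 2932 and 789 with the block (1 of 64, 6 pairs exchanged).

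Single arrays lay far from the others of their group in 38 of 546 groups tested, and chance flags about 1 in 20 groups. Values are log2(signal + 20), with the mean of the group's other arrays in brackets. R848 replicate 4 was low for IFNB1 at 12.96 (15.18), IFNA2 at 8.65 (11.91), CXCL10 at 12.93 (15.16), CD40 at 12.30 (14.43), IFIT5 at 12.51 (14.54) and IL6 at 14.32 (15.35). It was also low for DNAJA1 at 14.00 (14.94), DUSP1 at 14.59 (15.26), MAPK8 at 13.11 (13.75), ALDOA at 14.78 (15.27) and the mean of the IRF5-linked genes at 12.43 (13.94). The same number was low in DMSO for CCL4 at 13.50 (14.55) and RMI2 at 6.08 (7.02), and with the inhibitor for SOWAHC at 9.26 (10.51).

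Inhibitor replicate 1 was low for the mean of the NK cell markers at 8.31 (9.92), with KLRB1 at 9.39 (10.80) and PRF1 at 10.40 (11.85). It was also low for the platelet markers PF4 at 10.32 (12.37), GP9 at 5.74 (7.30) and TREML1 at 7.11 (9.25), and for CLEC12A at 11.18 (12.49) and BIRC2 at 13.06 (13.89). DMSO replicate 1 was low for CLEC12A at 10.11 (11.89) and high for RPL37 at 16.07 (15.26), and R848 replicate 1 was low for TREML1 at 5.90 (9.05). In R848 arrays, GP9 was low in replicate 5 at 5.07 (7.32), LEF1 in replicate 2 at 4.75 (6.88), LTF in replicate 2 at 5.77 (7.69), TNFRSF17 in replicate 8 at 6.42 (7.36) and HSPA6 in replicate 9 at 11.42 (12.65), and SLC4A1 was high in replicate 9 at 8.06 (6.44). In DMSO arrays, RGS16 was low in replicate 7 at 5.20 (7.47), and IFNA14 in replicate 5 at 5.47 (4.55), IFNA17 in replicate 3 at 5.98 (4.71) and IFNA4 in replicate 6 at 5.33 (4.61) were high. With the inhibitor, CASTOR1 at 8.90 (8.05) and MMP8 at 8.48 (7.70) were high in replicate 5, and LAMP3 was low in replicate 9 at 10.22 (11.60).

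Probe sets outside the comparisons also carried a response. Of 1141 with several gene symbols, 152 were higher and 133 lower with R848 than in DMSO, and of 4230 with no symbol 438 were higher and 732 lower, with 247 and 389 changed at least 2-fold. Between inhibitor and R848, 9 of the probe sets with no symbol were higher and 33 lower.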

How the results depend on the processing

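Scaling to the hybridization spikes, leaving number 4 or 9 out of every group, camera after 1 median of the genes tested, and camera with the block and an estimated correlation were chosen after the data were examined. So were the bootstrap of whole numbers for the share left and the simulated unchanged groups fitted with the block for the overlap. The cause of a change was not tested unless a clause says so.

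For R848 against DMSO, 2704 genes became 4778 with the number as a block, 4715 with a random block, 6557 under spike scaling, 1662 at an adjusted p of 0.01, which is a stricter threshold, and 6806 with every probe set on its own, which counts more features. For inhibitor against R848, 45 became 262 with the block, 312 with a random block, 101 with the 6 complete numbers and the block, 72 with 1 median of the genes tested, 80 with array weights, 25 under spike scaling, 140 with every probe set and 24 at an adjusted p of 0.01. For inhibitor against DMSO, 1391 became 2932, 3121 and 2481 in the same 3 fits with the number, 3957 under spike scaling, 3309 with every probe set and 714 at an adjusted p of 0.01. Quantile normalization gave 2428, 61 and 1402, within 1.5 times. With 1 array left out the counts ran from 2266 (without DMSO replicate 7) to 2815 (without DMSO replicate 4), from 31 (without inhibitor replicate 9) to 73 (without R848 replicate 4), and from 1043 (without DMSO replicate 7) to 1544 (without DMSO replicate 4).

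The 38 genes up with R848 and down with the inhibitor became 141 with the block, 156 with a random block, 74 with the 6 complete numbers, 63 with 1 median, 61 with array weights, 23 under spike scaling and 3 with the R848 arrays split, which leaves fewer arrays. They ran from 29 (without R848 replicate 7) to 61 (without R848 replicate 4). The 4 genes down and then up became 88, 110 and 18 with the number in the model, 8 with array weights, 2 with no filter, 1 under spike scaling, 1 without number 9 and 0 with the R848 arrays split, and ran from 1 (without inhibitor replicate 3, 8 or 9) to 8 (without R848 replicate 4), with 2 without R848 replicate 2, 3, 7 or 8 or inhibitor replicate 5. The share left ran from 74.8% (without inhibitor replicate 5) to 80.2% (without inhibitor replicate 1) for genes up, and from 70.1% (without inhibitor replicate 1) to 80.5% (without inhibitor replicate 5) for genes down, and it stayed within its bootstrap spread under every alternative run.

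Camera's 13 list calls for R848 against DMSO became 6 with an estimated correlation, with or without the block. For inhibitor against R848, 8 became 0 with an estimated correlation, 1 with the block added, 5 under quantile normalization and 0 with fry, which asks another question. With the block fry called 2 lists, interferon-stimulated (adjusted p = 0.016) and IRF5-linked genes (adjusted p = 0.00804). For inhibitor against DMSO, 11 became 7, and 6 with the block added. Under quantile normalization the ribosomal and monocyte lists turned downward, with adjusted p of 0.973 and 0.881 for R848 against DMSO and 0.871 and 0.871 for inhibitor against DMSO.

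Of named genes called for R848 against DMSO, 70 of 109 kept their calls in every alternative run for named genes, at an adjusted p of 0.05. The counts were 10 of 18 for inhibitor against R848 and 51 of 78 for inhibitor against DMSO. In the same order, 14, 0 and 3 called genes turned direction in at least 1 alternative. An adjusted p of 0.01, other minimum changes and every probe set on its own were not applied to named genes. The stricter filter by mean was applied only to the genes it kept. The block ended no call among the named genes called. For R848 against DMSO, quantile normalization gave ALDOA −0.0993, HSPA5 −0.0033, RPLP2 −0.0020, RPS16 −0.0029 and S100A8 −0.013. Spike scaling, which takes the rise of the spikes out of every gene by construction, gave ALDOA −0.19, ALDOC −0.0014, CD14 −0.0075, GAPDH −0.089, HSPA5 −0.15, MAPK8 −0.14, RPL37 −0.066, RPL7 −0.076, RPLP1 −0.10, RPLP2 −0.077, RPS14 −0.057, RPS16 −0.078, RPS7 −0.072 and S100A8 −0.12. For inhibitor against DMSO it gave HSPA5 −0.058, RPLP2 −0.050 and RPS14 −0.031. The mean of a gene's probe sets gave RPLP2 −0.11, RPS14 −0.30 and TPI1, which was not called as deposited (0.20), −0.41 for R848 against DMSO and RPLP2 −0.0080 for inhibitor against DMSO. Signal over background limits dim genes, since 7910 of 19775 were left out and the offset of 20 shrinks the changes of those near it.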

Other observations

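The test against T cell markers was chosen after the result was seen, while the other tests of the zinc finger genes were written down before it, and the gene family itself was picked from 70 symbol families after the data were examined.

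Zinc finger genes, whose symbols begin with ZNF and most of which encode DNA-binding proteins of the nucleus, fell with R848 more often than other genes. Of 365 tested, 181 were lower with R848, 9 higher and 175 not past the threshold, or 49.6% lower against 12.4% of other genes, and their median change was −0.63. The counts lower and higher were 233 and 15 with the block, 155 and 6 under quantile normalization, and 134 and 16 with 1 median of the genes tested. Camera gave the family an adjusted p of 5.58e-17 over 70 families, a call lost with an estimated correlation (adjusted p = 0.162 with an estimated correlation). The 37 ZBTB genes, a related family, gave 2 higher and 21 lower (median −0.66, adjusted p = 0.431 with an estimated correlation), and the 16 CLEC genes, lectins of the cell surface, gave 6 higher and 0 lower (adjusted p = 0.207 with an estimated correlation). The difference between these families was not tested. With the inhibitor, the ZNF median was 0.15 above R848 alone, and the 96 ZNF genes that fell at least 2-fold kept a median of 74.7% of that fall.

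Of the technical explanations for this fall, signal level, array scaling and T cell RNA were tested, and RNA quality was not tested against the ZNF genes. The array measures of RNA quality, the 3' to 5' signal ratios of GAPDH and ACTB, were 0.0073 and 0.157 (log2) higher on R848 than on DMSO arrays (exact permutation p = 0.861 and 0.381). The ZNF median lay 0.53 below that of other genes of the same level (difference −0.53, matched median −0.10), and the lowest median of 10000 random matched lists was −0.21, so a low signal level is argued against. Relative to the median of all genes it was −0.448 under quantile normalization, which argues against a difference in signal distribution between the arrays as the whole cause. A shift of whole arrays to 1 median cannot change that difference and tests nothing here. T cell markers lay 0.30 above the median of all genes (SD of their changes 0.32, 9 genes tested of 18 on the array). On these few genes, less T cell RNA in the R848 arrays is argued against. A candidate explanation is a biological response of these mRNAs to R848 within 1 h, a hypothesis, since the pattern was found and tested on the same data and is short of the threshold with an estimated correlation. Transcription and mRNA life were not measured, so neither was tested.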
